A study of Homo sapiens with 6 samples.

How the data were processed

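The data were RNA-seq libraries of MCF7 cells, an established breast cancer line, kept for 24 hours at 21% oxygen (normoxia) or 0.5% oxygen (hypoxia), with 3 libraries each. Per the labels' protocols, total RNA was extracted with TRIzol and treated with DNase, ribosomal RNA was depleted with RiboMinus, and cDNA was primed with random primers in the presence of actinomycin D, with dUTP in the second-strand mix. The count values were deposited by the authors as raw whole-number reads per Ensembl gene, with no normalization. The log2 values were deposited by the authors as 1 hypoxia over normoxia fold change per gene, and the sample descriptions name an edgeR result. Per the submitters' processing notes Bowtie 0.12.8 and the GRCh37 (hg19) genome were used. The read layout, the counting tool, whether strand was used in counting, and the model behind the deposited log2 values are not given in the sources used here. The series design text describes further experiments, which were not analysed here.

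The table held 23966 genes, each as 1 span in GRCh37, of which 3068 had no count in any library and 0 were mitochondrial. Names came from a gene symbol table for 23131 genes and from GENCODE release 29 alone for 101, and 734 had no match. Of all genes 6892 overlap another, 5585 of them one on the opposite strand, and reads in such spans cannot be assigned here. The 10 genes with most counts held 10.4%, 7.91% and 9.62% of counts in normoxia replicates 1, 2 and 3 and 15.5%, 9.24% and 13.6% in hypoxia replicates 1, 2 and 3. The 433 structured small RNA genes held between 3.19% and 4.66%. On the TMM-scaled CPM used for levels, a count of 1 corresponded to between 0.0278 and 0.0673 CPM, and a floor of 3 counts to at most 0.202 CPM.

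Libraries were grouped by oxygen tension. The titles number the libraries 1, 2 and 3 in both conditions, and these numbers were taken to mark a shared experiment. The characteristics give another experiment number, 1 for replicates 1 and 2 and 2 for replicate 3, and the sources do not say how both relate. In the deviations from the group means over genes, each library correlated best with the one of its own number in the other condition (across genes, r of 0.19, 0.33 and 0.10 for numbers 1, 2 and 3). Genes are not independent replicates, and deviations from a mean of 3 are tied to one another, so this was a check only.

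Genes were kept by filterByExpr (minimum count 10), which left 15060, and library sizes were scaled by TMM, with factors of 1.07, 1.12 and 1.08 for the normoxia and 0.771, 1.07 and 0.936 for the hypoxia libraries. Hypoxia was compared with normoxia by the two-sided quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, without a block, at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 0.224. The SE of a log2 change was its size divided by the square root of F. Levels are CPM with TMM-scaled library sizes, given as mean ± SD of 3 libraries. Counts were simulated for 3 libraries against 3, with 50 genes changed in each direction at each size. The edgeR fit recovered 52% of 2-fold rises and 52% of 2-fold falls, and 92% of 4-fold rises and 86% of 4-fold falls. Of its 152 calls, 11 were unchanged genes. DESeq2 recovered 72% and 64% at 2-fold, and 37 of its 199 calls were unchanged genes. The simulation changed few of the 15060 genes and none of those with the lowest counts, and it gave no pair or library a shared effect. These shares may therefore not hold for the real libraries.

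Of 31 gene lists written before the data were examined, 29 had enough tested members for camera in limma 3.58.1. It was run two-sided on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, with a Benjamini-Hochberg adjustment over the lists. Genes were called members of a change over all genes or with the adjustment over the list alone. The comparisons, tests, lists and alternatives but 1, and the rule for naming genes, were set before the data were examined. The rule took the 10 largest rises and the 10 largest falls among called genes with a symbol, a mean count of at least 50 and the same direction in 3 pairs. It always took TET1, TET2, TET3, DNMT1, DNMT3A, DNMT3B, HIF1A, EPAS1, CA9, VEGFA and ESR1. From each list it took the 2 risen and the 2 fallen members with the smallest adjusted p or, with none called, the 2 members with the smallest p.

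The alternatives were median-of-ratios and upper-quartile scaling, no filter for low counts, a mean count of at least 50, structured small RNA genes left out, the replicate number or the experiment number as a block, experiment 1 alone, each library left out in turn, and DESeq2 1.42.0. For the lists they were camera with an estimated correlation, fry, and lists without the core HIF targets. Total-count scaling, without normalization factors, was added after the data were seen, because the deposited fold changes lay lower than the fitted ones. A change of sign was counted as a reversal only where the main or the alternative result passed the threshold. Genes or libraries were not left out of the comparison for any other reason.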

Results

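RNA from MCF7 cells, an established luminal breast cancer line that expresses the estrogen receptor, was sequenced after 24 hours at 0.5% oxygen (hypoxia) or 21% oxygen (normoxia). Each condition had 3 libraries of total RNA depleted of ribosomal RNA, numbered 1 to 3 in both conditions. The deposited table held whole-number read counts for 23966 genes. The counts summed to 33532260, 22777031 and 27114886 in normoxia replicates 1, 2 and 3, and to 19291785, 22557683 and 20921975 in hypoxia replicates 1, 2 and 3. Levels are given as CPM, counts scaled to a common library total after TMM normalization, and 1 count corresponded to between 0.0278 and 0.0673 CPM. The series title puts the question in terms of TET enzymes, the oxygen-dependent dioxygenases that oxidise methylated cytosine, and their activity in hypoxic tumours. The RNA comparison asks which transcripts, those of the TET genes included, differ between the oxygen tensions.

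Hypoxic MCF7 cells carried far more RNA of ADM, IGFBP3 and LOX, genes of secreted or extracellular proteins. ADM, which encodes the vasodilator peptide adrenomedullin, was 81.1-fold higher, from 2.03 ± 2.41 to 173 ± 235 CPM (mean ± SD, n = 3 per group). IGFBP3, a secreted binding protein of insulin-like growth factors, was 77.5-fold higher, and LOX, the lysyl oxidase that crosslinks collagen, was 55.7-fold higher. The log2 rise of ADM was 6.34 with all 6 libraries, and over the alternatives its adjusted p ran from 2.71e-05 to 0.526. The 0.526 came from experiment 1 alone, where 0 genes passed and IGFBP3 and LOX had the same value. Single libraries moved the rises: that of ADM was 8.02 without normoxia replicate 1, where it no longer passed (adjusted p = 0.0710), and 4.12 without hypoxia replicate 1. IGFBP3 had 7.26, which missed the threshold, and 5.06 in these fits against 6.28, and LOX had 6.71 without normoxia replicate 1 against 5.80. Falls were smaller, led by the kinesin gene KIF12, 7.90-fold lower, from 42.5 ± 10.3 to 5.30 ± 2.67 CPM. Of 15060 genes tested with edgeR's quasi-likelihood test, 517 rose and 273 fell at a Benjamini-Hochberg adjusted p under 0.05. Of these, 381 rose and 112 fell at least 2-fold, and all 790 moved the same way in each of the 3 same-numbered pairs. They were called on these same libraries, so the shared direction is no separate support. With the replicate number as a block, 980 rose and 728 fell, and 788 of the 790 genes were among them. The 3 pairs differed in how far genes moved: the SD of the log2 change over all genes was 0.97, 0.57 and 0.75 in pairs 1, 2 and 3.

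**Figure D1:**
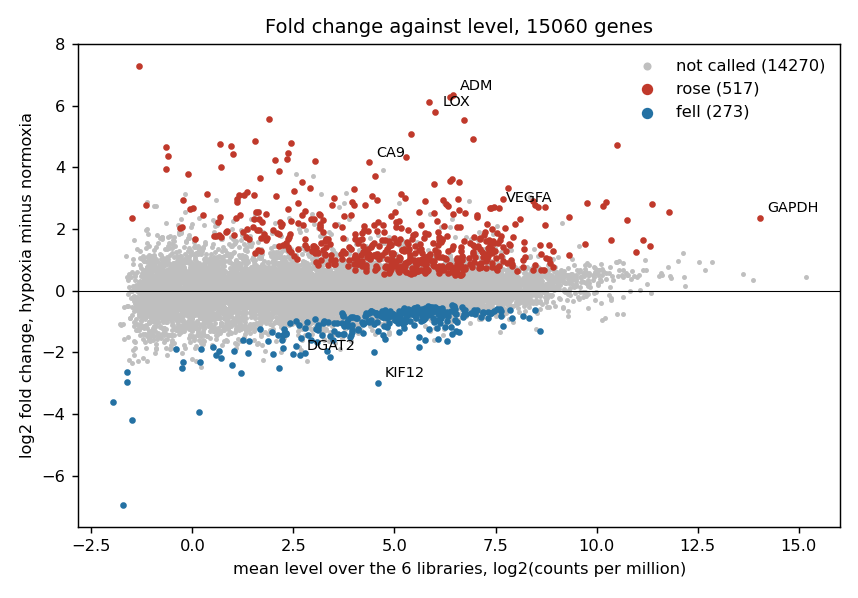
Fitted log2 fold change (hypoxia minus normoxia) against mean level over the 6 libraries, as log2 CPM, with 1 point per gene tested. Red points are the 517 genes that rose and blue points the 273 that fell at an adjusted p under 0.05, and grey points the 14270 that passed in neither direction.

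The number of genes past the threshold rested on single libraries, so each call for ADM, CA9 or any other gene holds for the 6 libraries together. It was 154 up and 21 down without normoxia replicate 1, 1 up and 1 down without normoxia replicate 2, 1 up and 0 down without hypoxia replicate 3, and 0 in both directions without normoxia replicate 3. In that last fit, also with edgeR, 1390 genes were higher and 1092 lower at an unadjusted p under 0.05, and LOX had a log2 change of 5.63 against 5.80 with all libraries and PGK1 one of 2.78 against 2.88. Without hypoxia replicate 2 the counts were 2249 up and 1936 down, with all 790 genes among them, and without hypoxia replicate 1 they were 549 up and 331 down, with 702 of the 790 genes among them. The labels also give an experiment number, 1 for replicates 1 and 2 and 2 for replicate 3. With it as a block, 76 genes rose and 23 fell. Within experiment 1 alone, 2 libraries against 2, edgeR called 0 genes in either direction, with 828 higher and 481 lower at an unadjusted p under 0.05. Many genes shared 1 adjusted p there, so where this fit gives the upper end of a gene's range, that end tells little about the gene. Experiment 2 held 1 library of each condition and allowed no test.

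Among genes with a mean count of at least 50, the 10 largest rises were shared between secreted or matrix proteins and genes of other kinds. ADM rose by 6.34 ± 1.34 on the log2 scale (SE, n = 3 per group, adjusted p = 0.0371), IGFBP3 by 6.28 ± 1.19 (adjusted p = 0.0265), and ANKRD37, an ankyrin-repeat protein gene, by 6.13 ± 1.41 (adjusted p = 0.0449). LOX rose by 5.80 ± 0.66 (adjusted p = 0.0107) and its relative LOXL2 by 5.52 ± 0.72 (adjusted p = 0.0111). The others were the noncoding RNA LINC03047, FAM13A, the lipoprotein lipase inhibitor gene ANGPTL4, the semaphorin gene SEMA5B and the sodium channel subunit gene SCNN1G, with log2 rises from 4.78 to 5.57. In normoxia replicates 1, 2 and 3 LINC03047 had 12, 0 and 2 counts and SEMA5B 11, 2 and 5. These lie partly under the floor of 3 counts, so the size of both rises is uncertain. Without hypoxia replicate 1 the rise of ANKRD37 was 3.64, of LINC03047 4.45, of FAM13A 4.11 and of SCNN1G 3.88, and ANGPTL4 had a change of 3.61 that missed the threshold. Without normoxia replicate 1 the changes were 7.25 for ANKRD37, 7.43 for LINC03047, 6.63 for ANGPTL4, 6.29 for FAM13A and 6.44 for LOXL2, and the first 3 of these missed the threshold. ADM lies at 10326227 to 10328944 on chromosome 11, IGFBP3 at 45951949 to 45961473 on chromosome 7 and LOX at 121398890 to 121413980 on chromosome 5 (GRCh37). KIF12 fell by 2.98 ± 0.39 (adjusted p = 0.0111), followed by INSYN1, the lipid droplet gene PLIN5, RIPOR3 and DGAT2, an enzyme of triglyceride synthesis, which fell by between 2.10 and 2.50. INSYN1 and PLIN5 had only 3 and 4 counts in hypoxia replicate 1. TM4SF18-AS1, SPRY4, CYP4F11, RAB37 and DOK7 fell by between 2.00 and 2.06. ANKRD37, LOX, FAM13A, ANGPTL4, DGAT2, TM4SF18-AS1, SPRY4 and RAB37 each overlap a gene on the opposite strand, and LOXL2 and PLIN5 one on their own strand, so their counts may hold reads of that neighbour.

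Known targets of the hypoxia-inducible factors (HIF) rose together. Of 42 tested members of the core HIF target list, 33 passed the test, all of them higher in hypoxia, and 39 passed when adjusted over the list alone. CA9, the carbonic anhydrase used as a marker of hypoxia, rose by 4.16 ± 0.72 on the log2 scale (adjusted p = 0.0202), or 17.9-fold. VEGFA, the main angiogenic growth factor, rose by 2.70 ± 0.57 (adjusted p = 0.0373), and by 1.67 without hypoxia replicate 1, which held 671 CPM against 118 and 208 in hypoxia replicates 2 and 3. The smallest adjusted p values of the list belonged to the nuclear receptor gene RORA, which rose by 1.82 ± 0.17, and to P4HA2, a collagen prolyl hydroxylase, which rose by 2.46 ± 0.27. The list lay above the other genes in limma's camera test, with a median log2 change of 2.66 (adjusted p = 1.1e-23 with the preset correlation, adjusted p = 0.359 with an estimated correlation). With an estimated correlation camera called 0 of the 29 lists. It gave several lists this same 0.359, the interferon-stimulated genes included, so the value is not particular to the HIF targets. Genes of this kind were not at 1 level in normoxia: CA9 stood at 4.95, 0.471 and 0.921 CPM in normoxia replicates 1, 2 and 3. Without normoxia replicate 1, where CA9 was highest, its log2 rise was 5.78, and 23 of the 42 members passed.

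**Figure D2:**
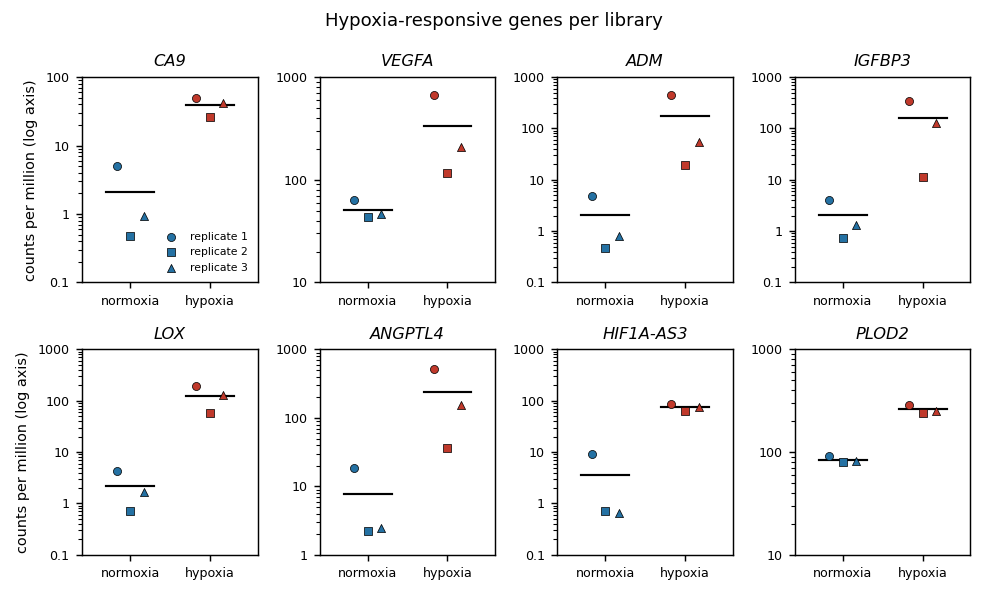
Level per library, in CPM on log axes, of 8 genes that rose in hypoxia. Circles, squares and triangles are replicates 1, 2 and 3 and horizontal lines the means; all 3 hypoxia libraries lie above all 3 normoxia libraries for each gene, while ADM ranges from 19.4 to 443 CPM among the hypoxia libraries and PLOD2 only from 242 to 285.

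Most glycolysis genes rose with the HIF targets, as did a part of the genes for fuel storage and collagen modification. Of 21 genes for glycolysis and lactate export, 17 passed, all as rises, and 20 when adjusted over the list alone. PGK1 rose by 2.88 ± 0.34 (adjusted p = 0.0107) and ENO1 by 1.65 ± 0.21 (adjusted p = 0.0111). Both encode enzymes of the lower, energy-yielding part of the pathway. Among 10 genes for glycogen and lipid droplet storage 5 rose, 9 when adjusted over the list alone, led by PGM1 with 1.74 ± 0.19 and the glycogen branching enzyme gene GBE1 with 2.69 ± 0.30. The lipid droplet gene PLIN5 and the triglyceride synthesis gene DGAT2, which fell as given above, are not on this list. Among 12 genes for collagen hydroxylation and crosslinking 7 rose, and 9 rose and 1 fell when adjusted over the list alone. PLOD2, a collagen lysyl hydroxylase, rose by 1.62 ± 0.13, with P4HA2, LOX and LOXL2 already named. The core HIF target list also holds 4 of the 17 glycolysis genes that rose and 4 of the 7 collagen genes. All 3 lists lay above the other genes (camera, adjusted p = 5.2e-14, 4.2e-06 and 7.9e-06, and adjusted p = 0.359 for each with an estimated correlation). The counts of rises were 8, 3 and 5 without normoxia replicate 1, while without hypoxia replicate 2 they were 20, 9 and 9. With the replicate block 8 of the 10 storage genes rose.

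The transcripts of the TET and DNMT enzymes, which remove and place cytosine methylation, did not pass the edgeR test of the 6 libraries without a block. TET1 had a log2 change of 0.33 ± 0.21 (adjusted p = 0.342), from 25.9 ± 3.02 to 32.7 ± 8.33 CPM. Its log2 change was -0.28, 0.40 and 0.79 in pairs 1, 2 and 3. TET2 had one of 0.74 ± 0.22 (adjusted p = 0.0925), from 101 ± 14.8 to 168 ± 53.1 CPM. In pairs 1, 2 and 3 TET2 had log2 changes of 1.45, 0.37 and 0.30, so most of its rise came from pair 1. It stood at 229 CPM in hypoxia replicate 1 against 143 and 133 in hypoxia replicates 2 and 3. TET3 had one of -0.32 ± 0.20 (adjusted p = 0.361), from 101 ± 16.8 to 80.7 ± 20.6 CPM. The maintenance methyltransferase gene DNMT1 had a log2 change of -0.48 ± 0.17 (adjusted p = 0.128) and DNMT3A one of 0.04 ± 0.14 (adjusted p = 0.866). DNMT3B, a de novo methyltransferase gene, had a log2 change of -0.89 ± 0.22 (adjusted p = 0.0539), and it passed with the replicate block (adjusted p = 0.0157). Over the alternatives tried its adjusted p ran from 0.00182, without hypoxia replicate 2, to 0.578. In that same fit TET2 passed as higher (adjusted p = 0.0207, range over the alternatives 0.0207 to 0.547) and TET3 as lower (adjusted p = 0.0453, range over the alternatives 0.0453 to 0.794). DNMT1 passed there as lower, with a log2 change of -0.68 (adjusted p = 0.00572, range over the alternatives 0.00572 to 0.634). In DESeq2 TET2 passed as higher (adjusted p = 0.0281) and DNMT3B as lower (adjusted p = 0.00481). TET1 lies at 70320413 to 70454239 on chromosome 10, TET2 at 106067032 to 106200973 on chromosome 4 and TET3 at 74229840 to 74335303 on chromosome 2 (GRCh37).

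Among all 19 genes for DNA methylation and demethylation edgeR called 0, also when adjusted over the list alone. At an unadjusted p under 0.05, 4 were higher and 2 lower, DESeq2 called 1 in each direction, and so did edgeR with the replicate block. The member with the largest change was the stress-inducible gene GADD45B, at 2.06 ± 0.62 (adjusted p = 0.0922), which stood at 255, 44.2 and 47.1 CPM in hypoxia replicates 1, 2 and 3. Without hypoxia replicate 1 its log2 change was 0.73 and passed (adjusted p = 0.0236), and it passed without hypoxia replicate 2 (adjusted p = 0.00808, range over the alternatives 0.00808 to 0.529). The list did not stand apart from other genes (camera, median log2 change 0.04, or -0.20 under total-count scaling, adjusted p = 0.774). Without hypoxia replicate 2, 5 members rose and 4 fell, and without hypoxia replicate 1, 1 rose.

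**Figure D3:**
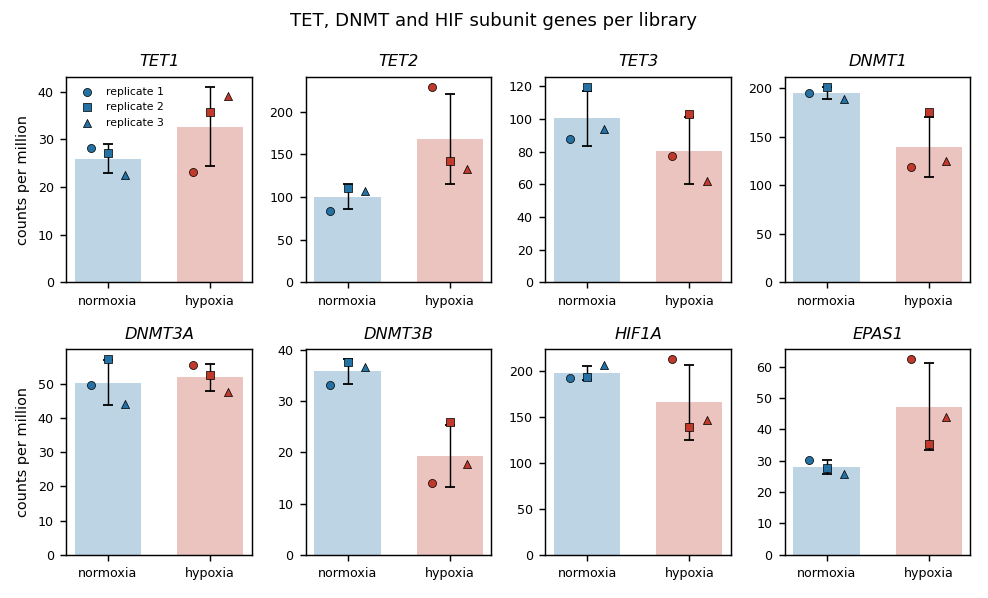
Level per library, in CPM, of the TET, DNMT and HIF subunit genes. Bars are means, error bars SDs of 3 libraries, and circles, squares and triangles replicates 1, 2 and 3; none of the 8 genes passed at an adjusted p under 0.05 in edgeR without a block, and DNMT3B came nearest, at 35.8 ± 2.37 CPM in normoxia and 19.2 ± 6.08 CPM in hypoxia.

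A few other oxygen-dependent dioxygenase genes rose in hypoxia. Of 20 genes for histone demethylases and HIF hydroxylases 4 rose, namely KDM3A, EGLN1, KDM4C and EGLN3, and 14 rose when adjusted over the list alone, while 4 had a negative change (camera, median 0.59, adjusted p = 4.9e-06, adjusted p = 0.359 with an estimated correlation). All 4 called genes are on the core HIF target list too, so they add no rise to it. KDM3A, a demethylase of histone H3 lysine 9, rose by 2.15 ± 0.31 (adjusted p = 0.0140), and EGLN1, the main prolyl hydroxylase of HIF, by 1.77 ± 0.23 (adjusted p = 0.0111). The replicate block gave 10 rises, leaving out hypoxia replicate 2 gave 13 and leaving out normoxia replicate 1 gave 2. KDM4C and EGLN3 were named after their values were seen, to complete the count.

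HIF1A, the oxygen-regulated HIF subunit gene, had a log2 change of -0.25 ± 0.18 (adjusted p = 0.408), and passed as lower without hypoxia replicate 1, at -0.47 (adjusted p = 0.0466, range over the alternatives 0.0466 to 0.882). EPAS1, which encodes the second such subunit, had one of 0.76 ± 0.21 (adjusted p = 0.0720). It passed with the replicate block (adjusted p = 0.0289), in DESeq2 (adjusted p = 0.0172) and without hypoxia replicate 2 (adjusted p = 0.00492, range over the alternatives 0.00492 to 0.578). Among 14 HIF subunits and regulators 4 rose, and 5 rose and 1 fell when adjusted over the list alone (camera, median 0.33, adjusted p = 0.0154, adjusted p = 0.359 with an estimated correlation). The list test missed the threshold without hypoxia replicate 1 (adjusted p = 0.0637), without hypoxia replicate 2 (adjusted p = 0.0540) and with the core HIF targets taken out of the list (adjusted p = 0.116), in a range over the alternatives of 0.00532 to 0.359. Of the 4 that rose, 2 are on the core HIF target list. CITED2, a transcriptional inhibitor of HIF, rose by 2.98 ± 0.48, and by 2.304 without hypoxia replicate 1. HIF1A-AS3, a noncoding gene on the strand opposite HIF1A, rose by 4.35 ± 0.88 (adjusted p = 0.0312), or 20.4-fold, and by 6.77 without normoxia replicate 1. Its 3 hypoxia libraries held 1288, 1516 and 1473 counts against 336, 18 and 19 in normoxia replicates 1, 2 and 3. It overlaps HIF1A, whose reads cannot be told from its own if strand was not used. HIF1A held 6922, 4921 and 6038 counts in normoxia replicates 1, 2 and 3, and 3159, 3332 and 2861 in the hypoxia replicates. Scaled for depth, HIF1A stood at 192, 193 and 206 CPM in normoxia replicates 1, 2 and 3, and at 213, 139 and 146 CPM in the hypoxia replicates. These levels do not follow those of HIF1A-AS3, which argues against HIF1A reads as the source of the rise of HIF1A-AS3. If strand was not used, the HIF1A counts may in turn hold reads of HIF1A-AS3, so the change given for HIF1A is uncertain.

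Few genes of mitochondrial energy metabolism passed the test. Of 21 tricarboxylic acid cycle genes 2 fell, 5 when adjusted over the list alone, and none of the 21 passed as higher. IDH3A, a subunit of the cycle's NAD-dependent isocitrate dehydrogenase, fell by 0.82 ± 0.15 (adjusted p = 0.0241), and the pyruvate carboxylase gene PC fell by 1.00 ± 0.19 (adjusted p = 0.0281). The list lay below the other genes (camera, median -0.20, adjusted p = 0.00722, adjusted p = 0.544 with an estimated correlation), though not without hypoxia replicate 2 (adjusted p = 0.110, range over the alternatives 9.1e-05 to 0.544). Without normoxia replicate 1 edgeR called 0 of its members, and without hypoxia replicate 2 it called 5. Of 63 nuclear-encoded genes of electron transport and ATP synthase only NDUFS6, a complex I subunit, fell, by 0.62 ± 0.14 (adjusted p = 0.0419), and the list did not stand apart (camera, median -0.09, adjusted p = 0.116). Under total-count scaling, which shifted the median of all genes to -0.24, this list passed as lower (adjusted p = 4.7e-04), and it did so without hypoxia replicate 1 (adjusted p = 5.3e-04) and without normoxia replicate 2 (adjusted p = 0.0267), in a range over the alternatives of 4.7e-04 to 0.842. Without hypoxia replicate 2, 7 of its members rose and 3 fell, and no member passed without normoxia replicate 1 or when adjusted over the list alone.

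A part of the sterol synthesis genes rose, and a part of the ribosome biogenesis genes fell. Among 21 genes for cholesterol synthesis and sterol response 9 rose, 14 when adjusted over the list alone (camera, median 0.66, adjusted p = 4.9e-06, adjusted p = 0.359 with an estimated correlation). MVD, an enzyme of the mevalonate pathway, rose by 1.01 ± 0.16 (adjusted p = 0.0162) and SC5D, a late enzyme of cholesterol synthesis, by 0.93 ± 0.16 (adjusted p = 0.0213). Only 1 of these rises was left without normoxia replicate 1, and 15 rises and 1 fall were called without hypoxia replicate 2. Among 23 ribosome biogenesis genes 6 fell (camera, median -0.44, adjusted p = 3.3e-04, adjusted p = 0.359 with an estimated correlation), and 10 fell and 2 rose when adjusted over the list alone. RRP9, a component of small nucleolar ribonucleoproteins, fell by 1.27 ± 0.17 (adjusted p = 0.0134), and the nucleolar phosphoprotein gene NOLC1 fell by 0.72 ± 0.12 (adjusted p = 0.0208). The falls numbered 1 without normoxia replicate 1 and 15 without hypoxia replicate 2, where 4 members rose. The replicate block gave 8 falls and 2 rises.

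Estrogen receptor targets went both ways, with more falls than rises. Of 30 tested members 3 fell and 2 rose, and 8 fell and 2 rose when adjusted over the list alone. PGR, the progesterone receptor gene, fell by 1.50 ± 0.18 (adjusted p = 0.0107), and IGFBP4 fell by 1.26 ± 0.20 (adjusted p = 0.0174), with RET, named after its values were seen, as the other fall. STC2, also on the HIF target list, rose by 1.79 ± 0.28, and the cyclin gene CCND1 by 0.66 ± 0.15. The estrogen receptor gene ESR1 itself had a log2 change of -0.57 ± 0.30 (adjusted p = 0.277), from 691 ± 53.3 to 466 ± 225 CPM, and passed as lower without hypoxia replicate 2, at -1.03 (adjusted p = 0.00348, range over the alternatives 0.00348 to 0.748). The list lay below the other genes (camera, median -0.32, adjusted p = 0.0110, adjusted p = 0.359 with an estimated correlation) but missed the threshold under total-count scaling (adjusted p = 0.0673, range over the alternatives 0.00409 to 0.359). The replicate block gave 8 falls and 4 rises, leaving out normoxia replicate 1 gave 2 falls and no rise, and leaving out hypoxia replicate 2 gave 12 falls and 4 rises.

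**Figure D4:**
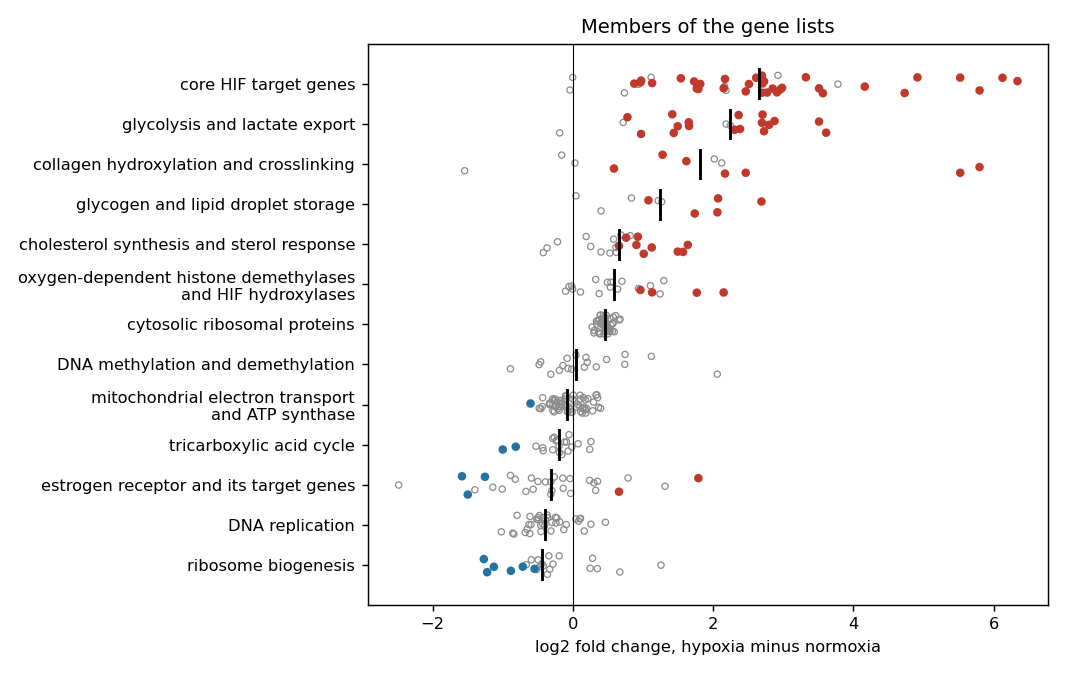
Log2 fold change (hypoxia minus normoxia) of the tested members of 13 gene lists, 1 point per gene. Filled red points rose and filled blue points fell at an adjusted p under 0.05, open points did not pass, and black bars are list medians, from 2.66 for core HIF targets to -0.44 for ribosome biogenesis.

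Proliferation genes had no called member in edgeR without a block, and a few with the replicate block or DESeq2. For 37 DNA replication genes edgeR called 0, with 10 lower and 1 higher at an unadjusted p under 0.05 and 3 lower and 1 higher by DESeq2. The list lay below the other genes (camera, median -0.40, adjusted p = 5.7e-04, adjusted p = 0.584 with an estimated correlation). Its medians were -0.78, -0.05 and -0.42 in pairs 1, 2 and 3, and without hypoxia replicate 2 the test called 23 falls and 1 rise, while without hypoxia replicate 1 it called 1 fall. POLE2, a DNA polymerase subunit gene, had a log2 change of -1.02 ± 0.26 (adjusted p = 0.0611) and passed with the replicate block (adjusted p = 0.0182, range over the alternatives 0.00317 to 0.571), which called 2 members lower. The licensing factor gene CDT1 had a change of 0.46 ± 0.12 (adjusted p = 0.0580). Of 32 mitotic genes edgeR called 0, with 2 higher and 2 lower at an unadjusted p under 0.05 and 1 lower by DESeq2 (camera, median 0.08, or -0.17 under total-count scaling, adjusted p = 0.451), and without hypoxia replicate 2, 3 rose and 1 fell. The centromere histone gene CENPA had a change of -0.55 ± 0.16 (adjusted p = 0.0808), which passed with the replicate block (adjusted p = 0.0310, range over the alternatives 0.00932 to 0.578), and TTK one of 0.38 ± 0.15. Of 26 genes for recombination, mismatch and crosslink repair edgeR and DESeq2 called 0, with 1 lower at an unadjusted p under 0.05, and 8 fell without hypoxia replicate 2. That repair list missed the threshold (camera, median -0.16, adjusted p = 0.0599) and passed with the replicate block (adjusted p = 0.0428), without normoxia replicate 1 (adjusted p = 0.0478) and without hypoxia replicate 2 (adjusted p = 0.00477, range over the alternatives 0.00477 to 0.778). MLH1 had a change of -0.34 ± 0.15 and RAD51C one of -0.49 ± 0.22. Without hypoxia replicate 2 POLE2, CDT1, CENPA, TTK, MLH1 and RAD51C each passed (adjusted p from 0.00317 to 0.0180), and POLE2 passed without hypoxia replicate 1 as well (adjusted p = 0.0384).

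Few genes of stress, survival and cell state lists passed, and only the autophagy and mitophagy list passed camera with the preset correlation. Of 27 unfolded protein and integrated stress response genes only VEGFA rose (camera, adjusted p = 0.774), joined by 2 falls with the replicate block. Of 22 p53 target genes DDB2 rose by 0.80 ± 0.18 and GDF15 by 1.27 ± 0.29 (camera, adjusted p = 0.451), and the replicate block gave 4 rises and 1 fall. Among 17 autophagy and mitophagy genes 3 rose, 7 when adjusted over the list alone (camera, median 0.55, adjusted p = 0.00399, adjusted p = 0.366 with an estimated correlation). The mitophagy receptor genes BNIP3L, up by 2.91 ± 0.41, and BNIP3, up by 2.77 ± 0.42, belong to the HIF target list as well, and the vesicle protein gene ATG9A, named after its values were seen, rose by 0.55 ± 0.13. TFRC, the transferrin receptor gene, rose from 241 ± 30.5 to 554 ± 57.5 CPM as the only one of 10 iron and heme genes (camera, adjusted p = 0.891), and with the replicate block 1 member fell, as 2 did when adjusted over the list alone or without hypoxia replicate 2. Of 13 interferon-stimulated genes edgeR called 0, with 3 lower at an unadjusted p under 0.05 and 2 lower by DESeq2 (camera, median -0.42, adjusted p = 0.0772). The list passed as lower without normoxia replicate 1 (adjusted p = 0.0485), without normoxia replicate 3 (adjusted p = 0.0259) and without hypoxia replicate 1 (adjusted p = 0.0255), in a range over the alternatives of 0.0047 to 0.359. Its nearest members were ISG15 with -1.07 ± 0.29 and IFIH1 with -0.84 ± 0.26, and IFIH1 passed with the replicate block (adjusted p = 0.0136, range over the alternatives 0.00764 to 0.592). Of 12 genes of epithelial and mesenchymal state edgeR called 0, with 2 higher and 1 lower at an unadjusted p under 0.05 and 1 in each direction by DESeq2 (camera, median 0.25, adjusted p = 0.164). MMP9 had a change of -1.32 ± 0.34 and VIM one of 0.89 ± 0.28. Without hypoxia replicate 2 ISG15, IFIH1, MMP9 and VIM each passed (adjusted p from 0.00764 to 0.0367), and the stress response list had 8 rises and 2 falls, the p53 list 7 and 1, the interferon list 1 and 3, the epithelial and mesenchymal list 3 and 1, and autophagy 8 rises. The p53 list had 1 rise without hypoxia replicate 1. Without normoxia replicate 1 edgeR called 0 genes of the stress response and p53 lists and 2 autophagy genes.

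Long noncoding RNAs, structured small RNAs and the messenger RNAs of ribosomal proteins and histones lay above the other genes in camera with the preset correlation. Of 17 long noncoding RNAs H19, an imprinted transcript, rose by 2.22 ± 0.31 and HIF1A-AS3 as given, and 10 rose and 1 fell when adjusted over the list alone (camera, median 0.43, adjusted p = 0.00238, adjusted p = 0.359 with an estimated correlation). With the replicate block 5 rose and 1 fell, and 9 rose and 1 fell without hypoxia replicate 2. For 47 cytosolic ribosomal protein genes edgeR called 0, with 13 higher at an unadjusted p under 0.05 and 2 higher by DESeq2, and all 47 had a positive fitted change. Their median was 0.46 (camera, adjusted p = 1.5e-07, adjusted p = 0.584 with an estimated correlation), or 0.17 under total-count scaling, where the median of all genes was -0.24. The median of these genes was 0.77, 0.08 and 0.41 in pairs 1, 2 and 3. RPS12 had a change of 0.59 ± 0.20 and RPS9 one of 0.66 ± 0.23, and 46 members rose without hypoxia replicate 2. For 19 replication-dependent histone genes edgeR called 0, with 5 higher at an unadjusted p under 0.05 and 1 by DESeq2 (camera, median 0.50, adjusted p = 0.00764, adjusted p = 0.584 with an estimated correlation). H2BC21 had a change of 1.13 ± 0.39, or 0.46 without hypoxia replicate 1, and H4C16 one of 0.43 ± 0.14. For 8 structured small RNAs edgeR called 0, with 1 higher at an unadjusted p under 0.05 and 2 higher by DESeq2 (camera, median 0.74, adjusted p = 0.0154, adjusted p = 0.584 with an estimated correlation). The spliceosomal RNA genes RNU1-1, with 1.11 ± 0.40, and RNU4-2, with 0.84 ± 0.40, were among 4 that rose with the replicate block (adjusted p = 0.00729 and 0.0218, ranges over the alternatives 0.00729 to 0.618 and 0.0218 to 0.642). Without hypoxia replicate 1 the histone and small RNA lists missed the threshold (adjusted p = 0.0551 and adjusted p = 0.149), as the small RNA list did without normoxia replicate 2 (adjusted p = 0.0831), in ranges over the alternatives of 0.00286 to 0.584 and 3.5e-04 to 0.584. Without hypoxia replicate 2, 12 histone genes and 6 small RNAs rose, with RPS12, RPS9, H2BC21, H4C16, RNU1-1 and RNU4-2 each past the threshold (adjusted p from 0.00446 to 0.0234).

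Markers of cell identity gave few calls. Of 15 luminal markers the keratin gene KRT19 rose by 1.16 ± 0.18 and AGR2 by 0.59 ± 0.12, and the list did not stand apart (camera, adjusted p = 0.899, with a median of -0.07 although the test leaned upward), with 2 rises and 1 fall when adjusted over the list alone, none without normoxia replicate 1, and 3 rises and 2 falls without hypoxia replicate 2. Of 6 tested basal epithelial and fibroblast markers CAV1 rose by 2.29 ± 0.24, EGFR rose by 2.51 ± 0.36 and TP63 fell by 1.67 ± 0.29, with 3 rises and 1 fall when adjusted over the list alone and no fall without normoxia replicate 1 (camera, adjusted p = 0.0772). The list passed as higher with the replicate block (adjusted p = 0.0366) and without normoxia replicate 3 (adjusted p = 0.0374, range over the alternatives 0.00588 to 0.445). CAV1 stood at 3.20 ± 0.63 CPM in normoxia and 15.7 ± 2.40 in hypoxia. Only the near-identical hemoglobin genes HBA1 and HBA2 of the blood and endothelial list had enough counts to test, at no more than 2.06 CPM in either group (camera, adjusted p = 0.0599, and adjusted p = 0.0304 without normoxia replicate 1, range over the alternatives 0.0174 to 0.889). They had changes of 0.93 ± 0.40 and 1.18 ± 0.44, and both edgeR and DESeq2 called 0 of them over all genes, while both passed at an unadjusted p under 0.05 and when adjusted over the list alone. The 1 testable hepatocyte marker, SERPINA1, had a change of 0.13 ± 0.41. Of 4 testable neural crest markers edgeR called 0, DESeq2 1 as lower, and at an unadjusted p under 0.05 TH was higher, at 0.94 ± 0.34, and GATA2 lower, at -0.75 ± 0.21 (camera, adjusted p = 0.891, leaning downward with a median of 0.15). In that list TH rose and GATA2 fell without hypoxia replicate 2 (adjusted p = 0.0237 and adjusted p = 0.0404), and 1 in each direction passed when adjusted over the list alone. Mitochondrially encoded genes are absent from the table.

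The authors' deposited table gives 1 log2 fold change per gene without an error. Over the 15060 tested genes, which are not independent replicates, those values had a Pearson r of 0.979 with the fitted ones, and none of the 790 called genes had the opposite sign. Both were taken to rest on the same libraries, so this closeness is no independent support. The authors' values were lower by a median of 0.35, and genes that were not called could differ in sign. TET1 had -0.03 there against 0.33 fitted, and DNMT3A -0.29 against 0.04. All 3068 genes with no count in any library carry the value 0.31 in the authors' deposited table.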

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

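Total-count scaling was the 1 alternative chosen only after the results were seen; the other tests were planned. No named gene or list reversed in any alternative. Against 517 rises and 273 falls, total-count scaling gave 241 rises and 192 falls, and 373 of the 790 genes passed in both. It shifted all genes, and ADM, VEGFA and 14 other named genes no longer passed. Rises and falls were 980 and 728 with the replicate block, 76 and 23 with the experiment block, 0 and 0 in experiment 1 alone (edgeR, 828 and 481 at an unadjusted p under 0.05, fewer libraries), and 1194 and 848 with DESeq2, which called 782 of the 790. With 1 library left out the rises ranged from 0 to 2249 and the falls from 0 to 1936. The experiment block called 99 of the 790 genes, and 35 of the 86 named genes no longer passed. A lost call did not need a smaller change: with this block ADM had a log2 change of 6.31 against 6.34, and INSYN1 one of -2.51 against -2.50. The cause of the lost calls was not tested.

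Median-of-ratios and upper-quartile scaling, no filter, a mean count of at least 50 and leaving out structured RNAs gave 508 to 675 rises and 269 to 379 falls. Of the 29 lists 16 passed with the preset correlation, and camera with an estimated correlation called 0. The fry test, which sets a list against no change and not against the other genes, called 13 by direction. The lists for ribosomal proteins, histones, structured small RNAs, DNA replication and the tricarboxylic acid cycle passed camera but not fry. The replicate block added DNMT3B, EPAS1 and 5 other named genes and changed no other call among the 86. Pseudocounts and a filter on normalized values were not run, since the file held counts, and DESeq2 gave no list tests. Depth limits genes of low level: 15060 of 23966 had enough counts to test.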

Other observations

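All tests below except the count of splits were chosen only after the results were seen, as were the genes and families named here that the report does not name. A few genes for mitochondrial ribosomal proteins and chaperonin subunits fell, and neither family was tested as a set. Of 62 mitochondrial ribosomal protein genes 7 fell, among them MRPL41 by 0.88 ± 0.13 and MRPL20 by 0.79 ± 0.12 on the log2 scale (SE, n = 3 per group), and 44 of the 62 had a negative change. The family's median was -0.21, and -0.46 under total-count scaling, where all genes shifted. With the replicate block 10 fell and 1 rose, without hypoxia replicate 2, 17 fell and 3 rose, and without normoxia replicate 1 edgeR called 0. Of 8 cytosolic chaperonin subunit genes CCT5 and CCT6A fell, each by 0.62 ± 0.14, and neither passed without normoxia replicate 1.

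Among single genes, SCARB1, the receptor for high-density lipoprotein, had the smallest adjusted p of all 15060 tested genes. It rose by 2.04 ± 0.13 (adjusted p = 0.00151), by 2.04, 1.94 and 2.13 in pairs 1, 2 and 3. SCD, the desaturase that makes monounsaturated fatty acids, rose from a mean of 1044 to 6095 CPM, though it missed the threshold without normoxia replicate 1 (adjusted p = 0.0514). PAM, which amidates peptide hormones such as the product of ADM, rose by 1.86 ± 0.16. HEY1, a target of Notch signalling, rose by 4.27 ± 0.46 and the cell cycle inhibitor gene CCNG2 by 2.25 ± 0.35. Of 6 genes of HLA class I 3 rose, including HLA-B by 2.13 ± 0.27 and HLA-C by 1.69 ± 0.25. The number was 5 without hypoxia replicate 2 and 1 without normoxia replicate 1, and reads of these genes are hard to tell apart. FGFR4, a receptor of fibroblast growth factors, fell by 1.34 ± 0.17.

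Genes with large rises were higher in normoxia replicate 1 than in the other normoxia libraries. Of 48 genes that rose at least 8-fold, 42 were highest in that library, with a median log2 ratio of 1.26 to the mean of the others, and CA9 had 178 counts there against 12 and 27. Of uncalled genes matched to these on level in normoxia 46.5% were highest there, against 33.3% of all uncalled genes and 87.5% of the 48. A low level therefore did not account for the whole. Uncalled genes may include some that respond to hypoxia, so whether a low level accounts for a part was not settled. Carry-over of reads from 1 hypoxia library may contribute and stays open. At most 36 of the 48 genes allowed 1 common share, 10.9% of hypoxia replicate 3, so no single share accounted for all of them. No biological explanation was tested, and mild hypoxia in that culture stays open.

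Over the risen genes as a set the response was smallest in pair 2. Not every gene followed this, since CA9 had log2 rises of 3.31, 5.57 and 5.39 in pairs 1, 2 and 3. The median log2 change of the risen genes was 1.54, 1.09 and 1.44 in these pairs. In pair 2 ADM had 466 counts in hypoxia against 6587 and 1076 in hypoxia replicates 1 and 3. The experiment number in the characteristics does not part the pairs this way, since the SD of the log2 change in pair 3, 0.75, lay between 0.97 in pair 1 and 0.57 in pair 2. If dilution of hypoxia replicate 2 with normoxic RNA were its only difference from another hypoxia library, all genes would have 1 share of the response. The shares of the risen genes were spread, as the quartiles below show, but library noise in them was not measured. Dilution could therefore not be told apart from a weaker response. Measured against hypoxia replicate 3, risen genes reached a median share of 0.619 and fallen genes 0.804 of the response, a difference of 0.185, and the fallen genes' median lay within the quartiles of the risen genes, 0.457 to 0.902. Against hypoxia replicate 1 it lay outside them, at 0.779 against 0.270 to 0.708. No biological explanation was tested.

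Cytosolic ribosomal protein genes such as RPS12 and RPS9 lay above the other genes although edgeR called 0 of them, with 13 higher at an unadjusted p under 0.05 and 2 by DESeq2. Their longest annotated transcripts had a median of 1826 nt against 3817 nt for 12259 other protein-coding genes, at a median level of 706 against 29.5 CPM. Whether part of the shift follows from this was not settled. Genes encoding no ribosomal protein, matched on transcript length and on mean level over both conditions, had a median log2 change of 0.24 (quartiles -0.01 to 0.63). It was 0.46 (quartiles 0.39 to 0.52) for the 47 members. Genes that rose in hypoxia could enter the match, and their rise is part of the level matched on, so the 0.24 may reflect them. The matched set was 192 different genes, and length was not separated from level. No biological explanation was tested.

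For the comparison of hypoxia with normoxia, the 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. The real split called 790 genes and was the only 1 with as many, and the highest other called 0 in edgeR (1655 at an unadjusted p under 0.05). Of the splits, 4 part all 3 same-numbered pairs, and the 3 others of these exchange the conditions within 1 pair.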
